A study of Mus musculus with 12 samples.

How the data were processed

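RNA from follicular (FO) and marginal zone (MZ) B cells of mouse spleen was sequenced from control and Zbtb24 conditional knockout (CKO) mice, with 3 libraries in each of the FO control, FO CKO, MZ control and MZ CKO groups. Per the labels, the cells were separated with a magnetic isolation kit for MZ and FO B cells, and libraries were made with the Illumina TruSeq RNA kit from 0.1 ug of total RNA. Each library carries an animal number in its label, and the same 6 numbers appear once among the FO and once among the MZ libraries. That the FO and MZ libraries of a number come from the same mouse is an inference from these labels.

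The deposited values are raw read counts per Ensembl gene, and the authors' processing notes name TopHat for alignment, HTSeq for counting and DESeq2, without versions, on genome build GRCm38. The annotation release used for counting is not given in the sources used here. Gene symbols and coordinates were taken from Gencode mouse release M21 on the same build. The deposited counts are whole numbers with no normalization, for 46078 genes, of which 45143 had a symbol in that annotation and 33106 had a count in at least 1 library. The last 5 entries of the file, which count reads that name no gene, were left out of every test. The alignment and counting were not repeated, so their parameters could not be checked.

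Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups of the comparison, libraries were scaled by TMM, and the quasi-likelihood F test was run with robust dispersion estimates. All tests of single genes were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the comparison. The comparisons were CKO against control in the 6 FO libraries, CKO against control in the 6 MZ libraries, MZ against FO in the 6 control libraries, MZ against FO in the 6 CKO libraries, and the difference between both genotype effects in all 12 libraries. Levels are CPM (edgeR cpm, counts scaled by the TMM-adjusted library size), given as mean ± SD of 3 libraries. Errors of log2 fold changes are approximate standard errors (SE). Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and edgeR does not give it directly. For single genes an exact two-sided permutation test was also run; 3 libraries against 3 cannot give less than 0.1. Where a control group held no or few counts of a gene, the fold was computed from summed counts, with a floor of 3 counts over the group for a group at 0 and an exact 95% binomial interval otherwise. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

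The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule takes Zbtb24 and Cdca7, then in each direction the 10 genes with the largest fold change among those that passed with at least 5 CPM in the higher group and no overlap between the groups' libraries. It leaves out predicted genes, pseudogenes and immunoglobulin V, D and J segments. It adds up to 4 members of each gene list that passed or, where no member passed, up to 2 with the smallest p. Other genes named in the text are said to be chosen after their values were seen.

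The 30 gene lists hold 362 genes, 360 of them in the file. They include genes mutated in ICF syndrome, genes reported in other cells as targets of ZBTB24, DNA methylation machinery, germline genes silenced by methylation, FO B cell markers, MZ B cell markers, the Notch2 pathway, inhibitory B cell receptors, immediate early and activation genes, class switch and end joining genes, plasma cell genes, endoplasmic reticulum (ER) chaperones, immunoglobulin constant genes, cytokine and TNF family receptors, Toll-like receptors, interferon-stimulated genes, cell cycle genes, p53 targets, MHC class II genes and heat shock genes. Further lists hold markers of T cells, NK cells, macrophages and monocytes, neutrophils, dendritic cells, erythroid cells and platelets, transitional and immature B cells, B-1 cells, and sex-linked genes. Each list was tested with camera on the edgeR fit with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in a shared direction without comparing them with other genes, was also run. Members past the test were counted over all genes tested and adjusted over the list alone. Results of 1 list and of some genes that the rule names are not reported here.

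Depth was read from the file as the sum of gene counts, 36340116 to 44629250 per library. To check recovery, counts were simulated for each comparison from its gene means and fitted dispersions, and changes were placed in genes above a minimum mean count. The simulated counts held the fitted spread of each gene but no differences between mice that are shared across genes. Recovery in the data may therefore be lower. At a fold of 2 the test recovered 58.2% of changed genes for the FO genotype comparison, 62.7% for MZ, 74.6% for MZ against FO in control mice, 58.2% in CKO mice and 47.8% for the difference between genotype effects. At a fold of 1.5 recovery was between 20.9% and 43.3%, and at a fold of 4 between 87.9% and 98.5%. Between 6.1% and 14.4% of the calls in the simulations were false.

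The alternatives were DESeq2 1.42.0 with its size factors and Wald test, limma 3.58.1 with voom, RLE factors in edgeR, immunoglobulin genes left out of the scaling, no filter on low counts, a filter of at least 5 CPM in 3 libraries, glmTreat against a fold of 1.5, all 12 libraries in the fit, the leading digits of the animal number (15 or 20) as a covariate in the genotype comparisons, the replicate number or the mouse as a block, and each library left out in turn. An edgeR fit without robust dispersion estimates was added after seeing the data. Replicate numbers were treated as pairs where the libraries of a number correlated above 0.1 once group means were removed. This held for FO control with FO CKO libraries (0.104, 0.323 and 0.361), and for FO with MZ libraries in control mice (0.426, 0.612 and 0.516) and in CKO mice (0.464, 0.651 and 0.604). FO control and FO CKO libraries of a replicate number carry different animal numbers, so their pairing rests on the correlations alone. No library was left out of the tests, and no pair of libraries within a group had the low spread of duplicated data.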

Results

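The data are 12 RNA sequencing libraries of splenic B cells from C57BL/6 mice aged 8 to 12 weeks. FO B cells are the recirculating B cells of the lymphoid follicles, and MZ B cells are an innate-like population at the border of the splenic white pulp that meets blood-borne antigens. Control mice carried the VAVcre transgene, which drives Cre recombinase in blood-forming cells, and CKO mice carried it with a conditional Zbtb24 allele. ZBTB24 is a zinc finger protein mutated in a form of ICF syndrome, a human disorder with immunodeficiency and low antibody levels. There were 3 libraries in each of the FO control, FO CKO, MZ control and MZ CKO groups. The depth, as the sum of gene counts, was 39502964, 41167006 and 40032502 in the FO control libraries and 43396215, 38530987 and 38422705 in the FO CKO libraries. It was 37831718, 44629250 and 36340116 in the MZ control libraries and 42193387, 40157059 and 37050034 in the MZ CKO libraries. Entries naming no gene held 43.2 to 50.4% of all listed reads per library. The leading principal component, which parted MZ from FO libraries, held 40.8% of the variance. The second held 17.7%. Its scores were positive (4.49 to 34.6) for mice 1505, 2003 and 2002 and negative (-0.0232 to -43) for mice 1507, 1512 and 1514. This parting of the mice is not by genotype and is described below.

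Zbtb24 (ENSMUSG00000019826, chromosome 10, 41450383 to 41465574), the targeted gene, was still counted in every CKO library. In FO B cells its level was 62.5, 60.8 and 60.8 CPM in control libraries and 48.3, 46.9 and 50 CPM in CKO libraries. In MZ B cells it was 49.1, 53 and 54.4 CPM in control libraries and 46.4, 41.8 and 41.9 CPM in CKO libraries. The CKO mean was 78.9 ± 2.56% of control in FO and 83.1 ± 5.04% in MZ B cells, and neither difference passed (log2 -0.34, SE 0.06, adjusted p = 0.1943 in FO; log2 -0.27, SE 0.08, adjusted p = 1 in MZ). Counts per exon were not analysed here, so reads from the part of the gene removed by Cre were not told apart from the rest. With DESeq2 the FO difference passed (adjusted p = 0.007683; range over the alternatives 0.007683 to 1).

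Cdca7 (ENSMUSG00000055612, chromosome 2, 72476159 to 72486893), an ICF gene that encodes a partner of the chromatin remodeller HELLS and a reported target of ZBTB24, was at 32.6 ± 1.12 CPM in FO control and 1.40 ± 1.10 CPM in FO CKO libraries. In MZ B cells it was at 36.4 ± 5.22 CPM in control and 3.33 ± 1.82 CPM in CKO libraries. The share of the control level left in CKO libraries was 3.08, 8.10 and 1.69% in FO and 7.57, 14.7 and 5.16% in MZ B cells. Every CKO library lay below every control library, and the exact permutation p was 0.1 in each cell type, the smallest that 3 against 3 allows. The edgeR test with robust dispersion did not pass (log2 -4.54, SE 0.60, adjusted p = 0.564 in FO; log2 -3.45, SE 0.42, adjusted p = 0.2909 in MZ). The DESeq2 test did (adjusted p = 6.687e-10 in FO and 4.606e-11 in MZ), as did limma-voom (0.008356 and 0.01296), and over the alternatives the adjusted p ranged from those DESeq2 values to 1. Without FO CKO replicate 2 the adjusted p for Cdca7 was 1.013e-05, and without MZ CKO replicate 2 it was 9.893e-05.

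**Figure D1:**
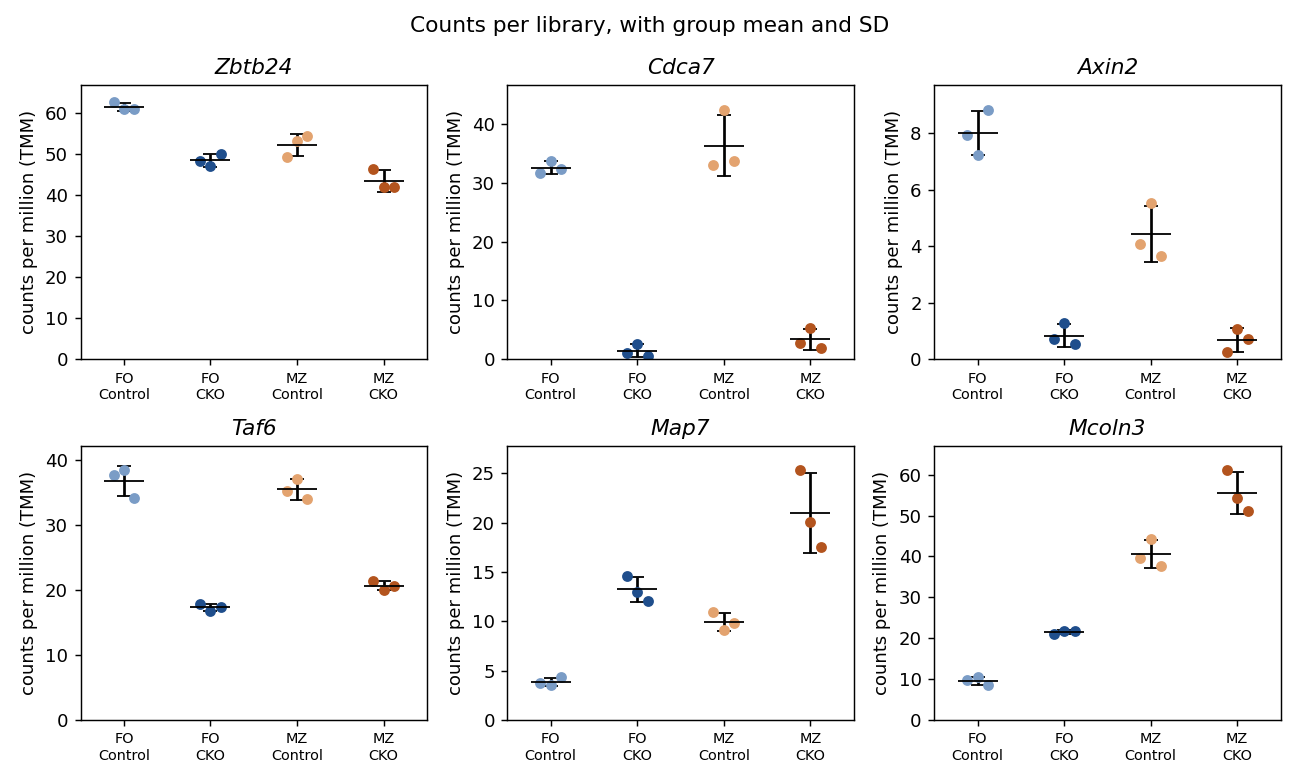
CPM (TMM scaled) of 6 genes in the 12 libraries, by group, with the group mean and SD of 3 libraries. Cdca7 stays between 0.55 and 5.37 CPM in CKO libraries of both cell types, against 31.7 to 42.4 CPM in control libraries.

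The FO genotype comparison asks which genes differ in follicular B cells when Zbtb24 is deleted in blood-forming cells. Axin2, a negative regulator of Wnt signalling, fell from 8.01 ± 0.792 to 0.834 ± 0.399 CPM in CKO libraries (log2 -3.26, SE 0.30, adjusted p = 0.004637; n = 3 per group). Taf6, a subunit of the general transcription factor TFIID, fell from 36.7 ± 2.32 to 17.3 ± 0.545 CPM (log2 -1.08, SE 0.08, adjusted p = 0.000606). Rnf187, which encodes an E3 ubiquitin ligase, fell from 187 ± 8.96 to 104 ± 8.51 CPM (log2 -0.85, SE 0.07, adjusted p = 0.001121). Map7, which encodes a microtubule-associated protein, rose from 3.85 ± 0.418 to 13.2 ± 1.31 CPM (log2 1.78, SE 0.14, adjusted p = 0.001071). Mcoln3, which encodes an endolysosomal cation channel, rose from 9.54 ± 0.981 to 21.4 ± 0.505 CPM (log2 1.17, SE 0.11, adjusted p = 0.001649).

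Of 17777 genes tested in FO B cells, 16 passed, 10 higher and 6 lower in CKO libraries, and 717 had an unadjusted p under 0.05 where chance alone gives 889. All 16 had no overlap between control and CKO libraries. Genes past the test are chosen for such separation, so the 10% that chance gives for any gene is no standard for them. The other genes that fell were the splicing factor gene Cdc40 (log2 -0.82), the oligosaccharyltransferase subunit gene Ostc (log2 -0.70) and the dystrobrevin gene Dtnb (log2 -0.57). The transcript BC018473 (log2 0.86), the adjacent sialyltransferase gene St6galnac1 (log2 0.86) and Hepacam2 (log2 0.78) rose. The remaining 5, chosen after their values were seen, were Gm26740 (log2 1.09), Sva, Hmgb1-ps8, Gm26581 and Gm5421. Sva had 0 counts in FO control and 154 in FO CKO libraries, at least 51.5-fold higher. The pseudogene Hmgb1-ps8 had 7 and 1810 counts (ratio 259, 95% interval 126 to 646), the lincRNA Gm26581 had 2 and 355 (ratio 178, 48.9 to 1480) and the pseudogene Gm5421 had 4 and 407 (ratio 102, 39.6 to 376). Axin2 missed the threshold without FO Control replicate 1 (adjusted p = 0.05744), and Dtnb, Hepacam2, Ostc and St6galnac1 each missed it without at least 1 of FO Control replicates 1 to 3 or FO CKO replicates 1 and 2, at up to 0.2576 for Ostc. Hmgb1-ps8 missed it without FO Control replicate 2 (adjusted p = 0.135) and without FO CKO replicate 1 (0.07695), 2 (0.05435) or 3 (0.05128). The count was 31 without FO CKO replicate 3.

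With the replicate number as a block, 25 genes passed in FO B cells, 18 higher and 7 lower, and all 16 were among them. The added genes, those other than Il5ra chosen after their values were seen, included Il5ra, the interleukin 5 receptor alpha chain (log2 1.07, adjusted p = 0.008221), the scavenger receptor gene Cd36 (log2 0.84, adjusted p = 0.007785), the asparagine synthetase gene Asns (log2 1.07, adjusted p = 0.02642), and Crisp3 (log2 1.85, adjusted p = 0.002849). The calprotectin genes S100a9 (log2 0.77, adjusted p = 0.004173) and S100a8 (log2 0.73, adjusted p = 0.04924), abundant in neutrophils, were also added. Without the block Il5ra was at 15 ± 4.16 CPM in FO control and 30.9 ± 3.89 CPM in FO CKO libraries (log2 1.04, SE 0.20, adjusted p = 0.732; 0.01041 without FO Control replicate 3).

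Among the 7 reported ZBTB24 targets, 4 fell in FO B cells (Axin2, Taf6, Cdc40 and Ostc) and 3 did not pass; adjusted over the list alone, 5 were lower and 1 higher. Camkmt, chosen after its value was seen, was at 2.97 ± 0.267 CPM in control and 4.02 ± 0.622 CPM in CKO libraries. The list as a group passed camera downward (adjusted p = 2.41e-47) and passed with an estimated correlation (adjusted p = 0.00331), though with the replicate block the latter was 0.141. The ICF genes (Zbtb24, Dnmt3b, Cdca7 and Hells) passed camera downward (adjusted p = 3.04e-07; adjusted p = 0.0737 with an estimated correlation), with 0 members past the test over all genes and 2 lower adjusted over the list alone. Dnmt3b, the DNA methyltransferase mutated in another form of ICF syndrome and chosen after its value was seen, was at 14.1 ± 0.351 CPM in control and 14.8 ± 0.454 CPM in CKO libraries.

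No member of the following groups passed in FO B cells without the block, though each group passed camera with the preset correlation; with the block Cd36 among MZ B cell markers and S100a8 and S100a9 among neutrophil markers passed. MZ B cell markers were shifted upward with a median log2 of 0.06 (adjusted p = 0.00018; adjusted p = 0.673 with an estimated correlation), Nebl being at 2.95 ± 0.962 CPM in control and 5.05 ± 0.716 CPM in CKO libraries. ER chaperones had a median log2 of 0.09 (adjusted p = 0.024; adjusted p = 0.416 with an estimated correlation). Interferon-stimulated genes had a median log2 of 0.41 (adjusted p = 4.69e-06; adjusted p = 0.716 with an estimated correlation), Oas1a being at 9.92 ± 2.0 CPM in control and 23.0 ± 8.92 CPM in CKO libraries. T cell markers had a median log2 of -0.30 (adjusted p = 2.41e-11; adjusted p = 0.673 with an estimated correlation), and Thy1 was at 44.5 ± 3.10 CPM in control and 32.3 ± 5.24 CPM in CKO libraries. Neutrophil markers had a median log2 of 0.99 (adjusted p = 2.49e-05; adjusted p = 0.673 with an estimated correlation), Retnlg being at 2.58 ± 0.469 CPM in control and 5.56 ± 1.66 CPM in CKO libraries. Adjusted over the list alone, Retnlg, Il5ra and the heat shock gene Hspe1 were higher and Cd5 was lower.

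In FO B cells the lists for DNA methylation machinery, germline genes, FO B cell markers, the Notch2 pathway, inhibitory receptors, activation genes, class switch and end joining, plasma cell genes, immunoglobulin constant genes, cytokine receptors, Toll-like receptors, cell cycle genes, p53 targets and MHC class II genes had 0 members past the test over all genes. The same held for heat shock genes and for markers of NK cells, macrophages, dendritic cells, erythroid cells and platelets, transitional B cells, B-1 cells and sex, except that with the block Il5ra, on the cytokine receptor and B-1 cell lists, passed. The camera adjusted p of these lists ranged from 0.0508 to 0.871. With the replicate block, heat shock genes (adjusted p = 0.0269), macrophage markers (0.0228) and dendritic cell markers (0.0228) passed camera, and 0 lists passed with an estimated correlation.

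The MZ genotype comparison asks the same of marginal zone B cells. Taf6 fell from 35.4 ± 1.58 to 20.6 ± 0.684 CPM in CKO libraries (log2 -0.78, SE 0.09, adjusted p = 0.005723; n = 3 per group), Ostc from 39.0 ± 0.713 to 23.1 ± 2.99 CPM (log2 -0.75), Cdc40 from 32.6 ± 0.778 to 20 ± 2.03 CPM (log2 -0.70) and Dtnb from 50.2 ± 2.03 to 34.0 ± 0.283 CPM (log2 -0.56). BC018473 rose from 79.3 ± 5.08 to 147 ± 1.95 CPM (log2 0.89, SE 0.07, adjusted p = 0.0006342), and Map7 rose from 9.95 ± 0.904 to 21 ± 4.05 CPM (log2 1.08, SE 0.15, adjusted p = 0.02464). Hepacam2 (log2 0.89) and the adenosine kinase gene Adk (log2 0.79, adjusted p = 0.04272) rose as well. Axin2 was at 4.43 ± 0.991 CPM in control libraries and at 15.3 ± 9.30% of that in CKO libraries, a difference that did not pass (log2 -2.71, SE 0.44, adjusted p = 0.2278).

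Of 17658 genes tested in MZ B cells, 14 passed, 10 higher and 4 lower in CKO libraries, and 512 had an unadjusted p under 0.05 where chance gives 883. All 14 had no overlap between the groups, which adds no separate support, as the test chose these genes for their separation. The genes outside the rule, chosen after their values were seen, were Gm26740 (log2 1.12), Crisp3 (log2 2.14, adjusted p = 0.03822), Sva with 0 counts in control and 164 in CKO libraries (at least 55.7-fold higher), Gm26581 with 0 and 293 (at least 99.5-fold higher), Hmgb1-ps8 with 8 and 1545 (ratio 197, 95% interval 99.6 to 456) and Gm5421 with 6 and 477 (ratio 81.0, 36.9 to 222). The count was 7 without MZ Control replicate 1, 5 without MZ Control replicate 2, 9 without MZ Control replicate 3 and 34 without MZ CKO replicate 3. Leaving out at least 1 of MZ Control replicates 1 to 3 or MZ CKO replicates 1 and 2 ended the calls of Adk (adjusted p up to 0.3394), Crisp3 (0.2901), Cdc40 (0.18), Dtnb (0.2217), Hepacam2 (0.1399), Map7 (0.1399), Ostc (0.1515), Gm26740 (0.07582) and Taf6 (0.06001), whereas BC018473, Sva, Gm26581, Gm5421 and Hmgb1-ps8 passed in each such fit.

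Among the 7 reported ZBTB24 targets, 3 fell in MZ B cells (Taf6, Ostc and Cdc40); adjusted over the list alone, 5 were lower. The list passed camera downward (adjusted p = 1.53e-32) and with an estimated correlation (adjusted p = 0.00883), though with the replicate block the latter was 0.135. ICF genes passed camera downward (adjusted p = 1.96e-05; adjusted p = 0.28 with an estimated correlation), with 0 members past the test over all genes and 2 lower adjusted over the list alone. Hells, which encodes a chromatin remodeller that acts with CDCA7, was at 21.9 ± 2.60 CPM in control and 25.3 ± 4.77 CPM in CKO libraries.

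No member of the other groups passed in MZ B cells without the block. With the replicate number as a block, 5 neutrophil markers, 1 cell cycle gene and Il5ra were higher and 1 dendritic cell marker was lower. In MZ B cells the replicate numbers do not pair the libraries. A split of the mice other than by genotype, described below, called the FO B cell markers Ccr7 and Itgb7 in MZ B cells. For the shift of that list, differences between the mice were not told apart from genotype. FO B cell markers were shifted upward with a median log2 of 0.20 (adjusted p = 5.9e-05; adjusted p = 0.574 with an estimated correlation), Fcer2a, the low-affinity IgE receptor CD23, being at 69.6 ± 4.29 CPM in control and 81.6 ± 10.8 CPM in CKO libraries. Interferon-stimulated genes had a median log2 of 0.25 (adjusted p = 2.46e-06; adjusted p = 0.616 with an estimated correlation), Oas1a being at 14.9 ± 1.64 CPM in control and 30.4 ± 8.19 CPM in CKO libraries (adjusted p = 0.321; 0.02904 without MZ CKO replicate 1). Cell cycle genes had a median log2 of 0.41 (adjusted p = 1.96e-05; adjusted p = 0.629 with an estimated correlation), p53 targets of 0.03 (adjusted p = 0.026; adjusted p = 0.374 with an estimated correlation) and immunoglobulin constant genes of 0.11 (adjusted p = 0.0175; adjusted p = 0.616 with an estimated correlation). Neutrophil markers had a median log2 of 1.16 (adjusted p = 0.00065; adjusted p = 0.616 with an estimated correlation), dendritic cell markers of -0.34 (adjusted p = 6.3e-06; adjusted p = 0.437 with an estimated correlation) and B-1 cell markers of 0.12 (adjusted p = 0.00418; adjusted p = 0.28 with an estimated correlation). Il5ra was at 19.0 ± 3.28 CPM in control and 35.5 ± 5.95 CPM in CKO libraries (log2 0.90, SE 0.15, adjusted p = 0.1993; 0.04949 without MZ Control replicate 3), and adjusted over the list alone it was higher, as were Bhlhe41 and Oas1a, while the plasmacytoid dendritic cell gene Siglech was lower. The remaining lists, MZ B cell markers, T cell markers and the Notch2 pathway among them, had camera adjusted p between 0.0571 for ER chaperones and 0.932 for erythroid and platelet markers.

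Among the 17177 genes tested in both cell types, 12 passed in FO and in MZ B cells, 8 higher and 4 lower, where independent lists would share 0.00582 and 0.0014. The shared genes that fell were Cdc40, Dtnb, Ostc and Taf6. The shared genes that rose were BC018473, Gm26581, Gm26740, Gm5421, Hepacam2, Hmgb1-ps8, Map7 and Sva. All 18 genes called in either cell type had the same sign in both. The FO and MZ libraries carry the same animal numbers, so differences between the mice are shared and the overlap is not that of independent samples. With DESeq2 the overlap was 24 genes, 16 higher and 8 lower, and included Axin2, Cdca7, Il5ra, Mcoln3 and Rnf187.

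**Figure D2:**
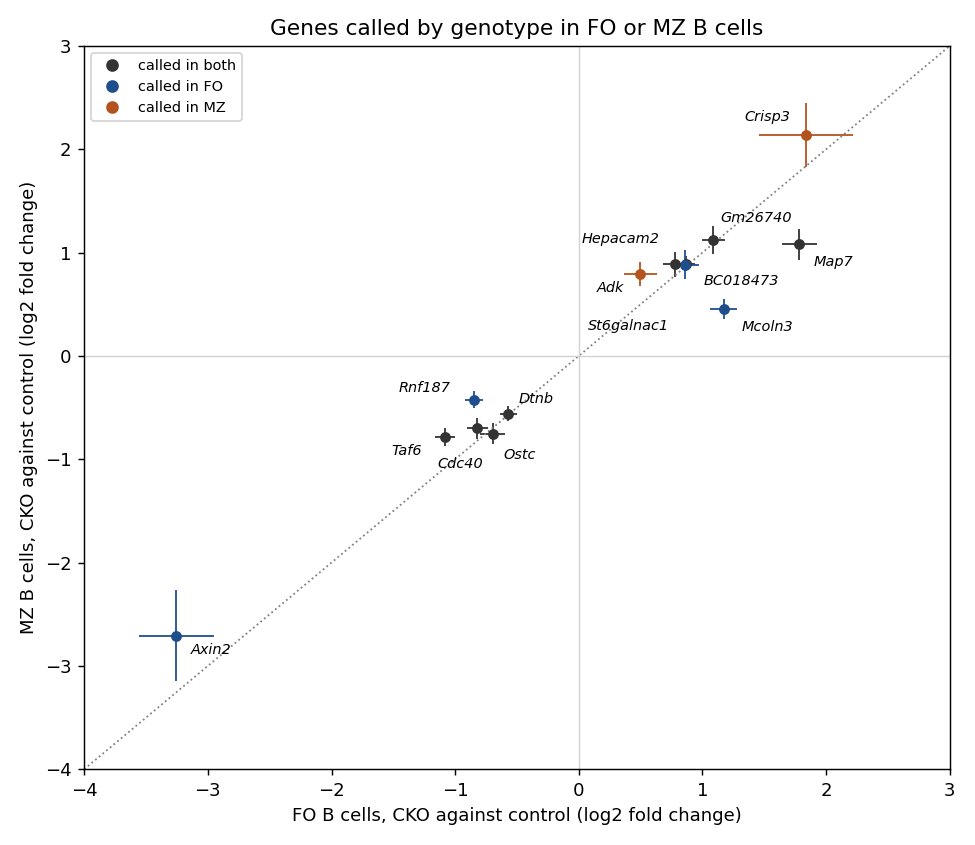
Log2 fold change of CKO against control in FO (horizontal) and MZ (vertical) B cells for 14 of the 18 genes called in either cell type, with bars for the SE. The 4 genes with almost no control counts, such as Sva, are left out; Axin2 is lowest in both, at -3.26 and -2.71.

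The called genes were placed on the genome. Of the 18 called in either cell type, 6 lay on chromosome 10, which also holds Zbtb24 and 776 of 18258 tested genes. With called genes within 1 Mb of each other counted once, these were 3 of 14 loci. Measured from the start of Zbtb24, Cdc40 started at -0.619 Mb, Map7 at -21.3 Mb, and Gm26740, Gm26581, Hmgb1-ps8 and Gm5421 between -19.3 and -19.1 Mb. The other 12 genes lay on 7 chromosomes.

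**Figure D3:**
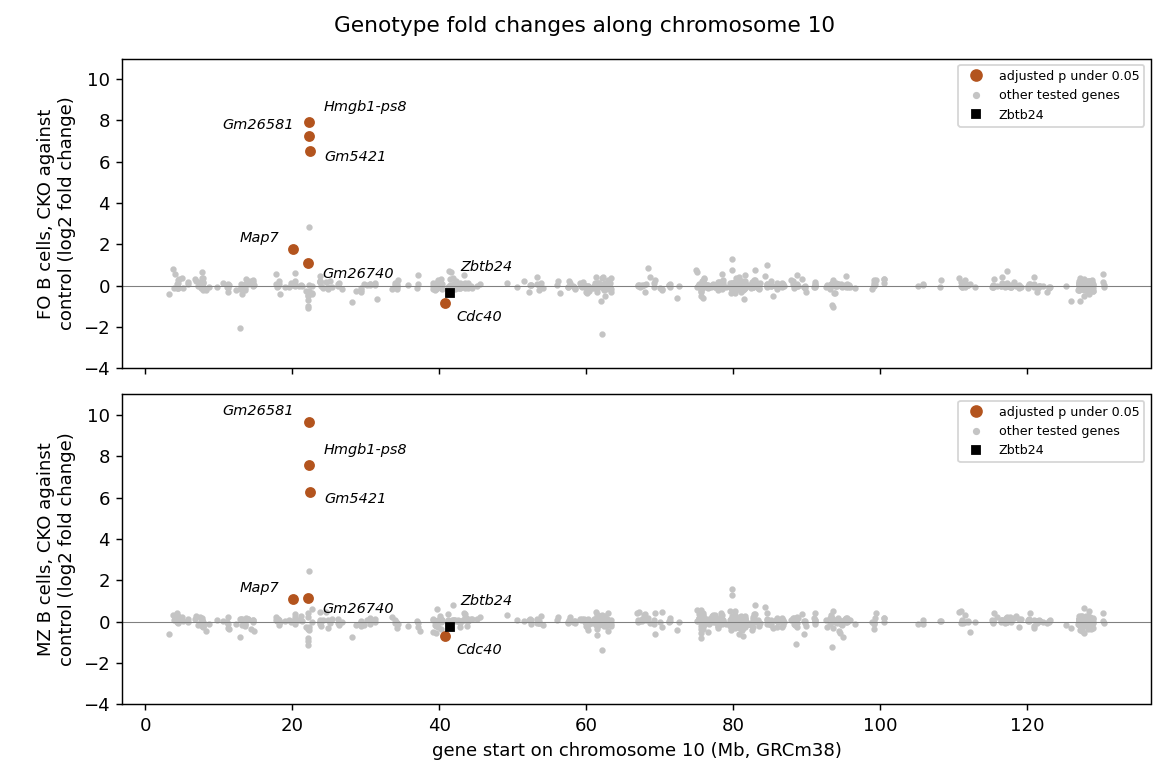
Log2 fold change of CKO against control along chromosome 10 (gene start in Mb, GRCm38) for the tested genes in FO and MZ B cells, with genes past an adjusted p of 0.05 in colour and Zbtb24 as a square. The called genes sit at Cdc40, next to Zbtb24, and around Map7 and Hmgb1-ps8, at -21.3 to -19.1 Mb from it.

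The comparison of MZ with FO B cells in control mice gives the differences between the subsets against which the CKO mice can be read. S1pr3, a sphingosine 1-phosphate receptor, was 24.6-fold higher in MZ B cells (276 ± 9.59 against 11.2 ± 1.76 CPM; log2 4.62, SE 0.11, adjusted p = 1.775e-09; n = 3 per group). Cr2, which encodes complement receptors CD21 and CD35, rose from 844 ± 148 CPM in FO to 3309 ± 220 CPM in MZ B cells (log2 1.97, SE 0.12, adjusted p = 2.628e-06). Fcer2a fell from 558 ± 33.5 to 69.6 ± 4.29 CPM (log2 -3.00, SE 0.08, adjusted p = 1.775e-09), and Ighd, the IgD heavy chain, from 1408 ± 150 to 353 ± 23.7 CPM (log2 -2.00, SE 0.09, adjusted p = 6.934e-08). The largest changes included Tsga13 (log2 6.43) and the atypical chemokine receptor gene Ackr3 (log2 5.65), which were higher, and the ryanodine receptor gene Ryr2 (log2 -3.72), Dusp4 (log2 -3.44) and the calcium channel gene Cacna1i (log2 -3.10), which were lower.

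In control mice 4977 of 17830 genes passed, 2653 higher and 2324 lower in MZ B cells. Of these 1240 differed by at least 2-fold, and 4934 had no overlap between the groups, which passing the test largely entails. With the mouse as a block 7805 genes passed, 3999 higher and 3806 lower, and NK cell (adjusted p = 0.0308) and neutrophil markers (0.028) were added to the lists past camera, both at 0.795 with an estimated correlation. Zbtb24 was lower in MZ B cells (log2 -0.24, SE 0.07, adjusted p = 0.01961), a call lost without FO Control replicate 1 (0.06088), FO Control replicate 2 (0.05388) or MZ Control replicate 1 (0.08291), and Cdca7 did not pass (log2 0.16, adjusted p = 0.2663).

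All 15 MZ B cell markers rose in control mice, with a median log2 of 2.32 (camera adjusted p = 1.82e-92; adjusted p = 0.0377 with an estimated correlation, and 0.45 with the mouse as a block), among them the tetraspanin gene Cd9 (log2 2.46) and Mzb1 (log2 1.62). Of the 10 FO B cell markers 9 fell, such as the transcription factor gene Bach2 (log2 -2.03), and Cxcr5 was higher (log2 0.38); the list passed camera (adjusted p = 4.64e-43; adjusted p = 0.0667 with an estimated correlation). Of 14 Toll-like receptor genes 10 rose, including Tlr3 (log2 2.93) and Tlr7 (log2 1.06), with camera adjusted p = 6.36e-07 (adjusted p = 0.328 with an estimated correlation). Of 10 MHC class II genes 5 fell, such as the transactivator gene Ciita (log2 -0.84), with adjusted p = 0.000328 (adjusted p = 0.802 with an estimated correlation). Markers of transitional B cells fell in 3 of 6 cases (Vpreb3, Sox4 and Cd93; adjusted p = 0.0043; adjusted p = 0.616 with an estimated correlation). T cell markers were lower in MZ libraries in 9 of 13 cases, Trbc1 at 18.5 ± 4.01 against 32.7 ± 3.74 CPM (adjusted p = 0.00011; adjusted p = 0.817 with an estimated correlation).

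Other lists went in both directions in control mice. In the Notch2 pathway 4 genes rose and 5 fell, Dtx1 (log2 2.29) and Hes5 (log2 1.91), which are targets of Notch signalling, being among those that rose and the glycosyltransferase gene Lfng (log2 -1.09) among those that fell (camera adjusted p = 0.525). Of the ER chaperones 5 rose and 4 fell, Pdia4 rising from 284 ± 16.3 to 1308 ± 24.2 CPM (log2 2.20; camera adjusted p = 0.132). Among activation genes 3 rose, including Myc (log2 1.13) and Cd86 (log2 1.20), and 6 fell (adjusted p = 0.493).

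The same comparison in CKO mice asks whether MZ and FO B cells still differ when Zbtb24 is deleted. S1pr3 was 21.7-fold higher in MZ B cells (257 ± 34.3 against 11.9 ± 3.94 CPM; log2 4.44, SE 0.28, adjusted p = 0.00043; n = 3 per group). Cr2 rose from 1043 ± 99.3 CPM in FO to 3187 ± 714 CPM in MZ B cells (log2 1.62, SE 0.17, adjusted p = 0.0003145), and the Notch target Dtx1 from 336 ± 59.5 to 1716 ± 51.0 CPM (log2 2.36, SE 0.13, adjusted p = 1.039e-05). Fcer2a fell from 547 ± 40.3 to 81.6 ± 10.8 CPM (log2 -2.74, SE 0.11, adjusted p = 4.558e-06), and Bach2 from 157 ± 3.48 to 43.0 ± 6.02 CPM (log2 -1.86, SE 0.10, adjusted p = 9.763e-06). Zbtb24 (log2 -0.15, adjusted p = 0.2147) and Cdca7 (log2 1.26, adjusted p = 0.2917) did not pass in this fit, which does not use the mouse. Cdca7 had 45, 105 and 21 counts in FO and 111, 211 and 68 in MZ CKO libraries of replicates 1 to 3. It passed without FO CKO replicate 2 (edgeR adjusted p = 0.04919). With the mouse as a block 2 ICF genes were higher in MZ B cells.

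In CKO mice 3243 of 17712 genes passed, 1865 higher and 1378 lower in MZ B cells. Of these 968 differed by at least 2-fold, and 3242 had no overlap between the groups, which passing the test largely entails. With the mouse as a block 6333 genes passed, 3396 higher and 2937 lower, and without FO CKO replicate 1 the count was 1898. Of 15 MZ B cell markers 14 rose, and 15 adjusted over the list alone (camera adjusted p = 1.16e-84; adjusted p = 0.0217 with an estimated correlation, and 0.417 with the mouse as a block). Of 10 FO B cell markers 9 fell and Cxcr5 rose (adjusted p = 2.93e-42; adjusted p = 0.0217 with an estimated correlation, and 0.417 with the block). Toll-like receptor genes rose in 8 of 14 cases (adjusted p = 2.6e-06; adjusted p = 0.339 with an estimated correlation), and MHC class II genes fell in 3 of 10 (adjusted p = 0.0054; adjusted p = 0.826 with an estimated correlation).

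The Notch2 pathway in CKO mice had 4 genes higher, such as Hes1 (log2 1.49), and 3 lower (camera adjusted p = 0.0207; adjusted p = 0.826 with an estimated correlation; camera with the block 0.099). The lists for inhibitory receptors (3 higher, 1 lower; adjusted p = 0.0262), T cell markers (2 lower; adjusted p = 0.00376) and NK cell markers (1 higher, 2 lower; adjusted p = 0.0433) passed camera too, each at adjusted p = 0.826 with an estimated correlation. With the block, inhibitory receptors were at 0.0666, and cell cycle genes (0.000934), neutrophil markers (4.55e-05) and transitional B cell markers (0.00467) passed camera, at 0.533, 0.432 and 0.533 with an estimated correlation. More single genes passed with the block: 12 T cell markers lower, 8 NK cell markers lower and 1 higher, and 15 cell cycle genes higher in MZ B cells.

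**Figure D4:**
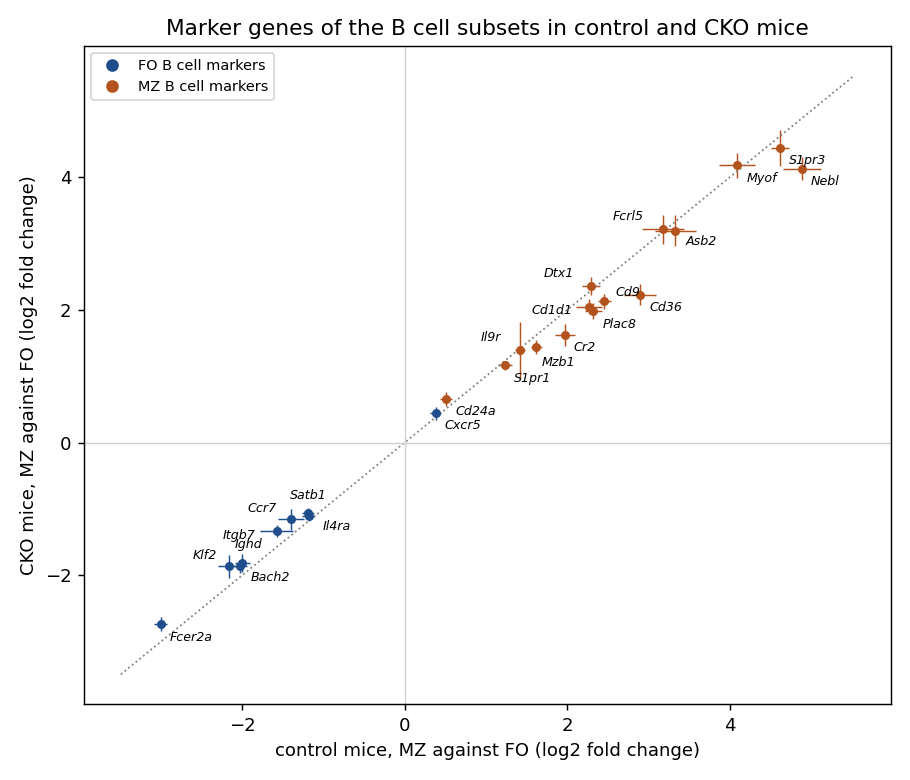
Log2 fold change of MZ against FO B cells in control mice (horizontal) and CKO mice (vertical) for 9 of the FO and all of the MZ B cell markers, with bars for the SE. S1pr3 is at 4.62 and 4.44, and Fcer2a at -3.00 and -2.74.

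Among 17415 genes tested in both genotypes, 4922 passed between MZ and FO B cells in control and 3220 in CKO mice. Of these 2803 passed in both, 1588 higher and 1215 lower, where independent lists would share 278 and 181, and all 2803 had the same sign. Pearson's r of the log2 fold changes was 0.894 across genes, which are not independent replicates.

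Whether the genotype effect itself differs between MZ and FO B cells was tested in all 12 libraries. Cdca7 had a difference of effects of log2 1.10 (SE 0.70, adjusted p = 1), and Zbtb24 of 0.08 (SE 0.09, adjusted p = 1). In edgeR 0 of 18546 genes passed, with 238 at an unadjusted p under 0.05 where chance gives 927. DESeq2 also gave 0 (224 unadjusted) and limma-voom 0 (247 unadjusted). These fits did not take into account that FO and MZ libraries carry the same animal numbers. With each mouse as a block 4 genes passed and 968 had an unadjusted p under 0.05. Of the genes that passed, those other than Cdca7 were chosen after their values were seen. The Mcoln3 effect was smaller in MZ than in FO B cells (difference in log2 -0.72, SE 0.11, adjusted p = 0.002535), as was the negative Cdca7 effect (difference 1.14, SE 0.17, adjusted p = 0.002535). The histone H4 genes Hist1h4a (0.63, adjusted p = 0.02964) and Hist1h4j (0.54, adjusted p = 0.04818) also differed. By camera the reported ZBTB24 targets, FO B cell markers, cell cycle genes and T cell markers had a higher and MZ B cell markers a lower effect in MZ B cells (adjusted p = 0.0482, 0.000587, 0.0142, 0.0142 and 0.000274). With an estimated correlation their adjusted p was 0.728, 0.728, 0.951, 0.9 and 0.728. A split of the mice other than by genotype, described below, called members of the FO B and T cell marker lists in MZ B cells. For those lists differences between the mice were not told apart from genotype. With the block, ICF genes (0.000155) and DNA methylation machinery (0.00241) passed camera too, and 0 lists passed with an estimated correlation.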

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

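The test of whether the genotype effect differs between the cell types was planned, and the tests of the explanations for Mcoln3 and Cdca7 were chosen after the result was seen. With each mouse as a block, 4 genes differed in their CKO effect between MZ and FO B cells. The differences in log2 effect, MZ minus FO, were -0.72 for Mcoln3, 1.14 for Cdca7, 0.63 for Hist1h4a and 0.54 for Hist1h4j. Without the block 0 genes passed, and for Cdca7 the adjusted p ranged from 0.002535 to 1 over the alternatives. The 10 splits of the mice are too few for a share under 0.05; the real split gave 4 genes, the highest other gave 5, and 3 of the 10 gave at least 4. Of the other splits, the 3 that part as many pairs of replicate numbers, which join different animals, gave 1, 1 and 0 genes.

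For Mcoln3, cells that escaped deletion among MZ B cells would have to make up 71% of the MZ CKO cells to give the smaller fold. The highest share of Cdca7 left in an MZ CKO library was 14.7%, which argues against escape as the cause of the Mcoln3 difference. On the linear scale Mcoln3 was 14.7 ± 3.63 CPM higher (SE) in MZ CKO and 11.9 ± 0.617 CPM higher in FO CKO than in control libraries, from control levels of 40.6 and 9.54 CPM, and the FO fold would have needed 50.9 CPM. The differing fold may therefore reflect a like rise in CPM over unequal control levels. For Cdca7 escape stays open, as Axin2 was left at 15.3 ± 9.30% of control in MZ and 10.4 ± 4.98% in FO CKO libraries, a gap within the spread; a difference between the cell types in how Zbtb24 acts on Cdca7 was not tested.

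The median difference in effect between MZ and FO B cells was 0.13 for the reported ZBTB24 targets, 0.17 for FO B cell markers, -0.18 for MZ B cell markers, 0.27 for cell cycle genes and 0.20 for T cell markers. These lists passed camera in the test of the difference with the preset correlation, and with an estimated correlation their adjusted p lay between 0.728 and 0.951. Ccr7 and Itgb7 among FO B cell markers and Cd3g and Trbc2 among T cell markers were called in MZ B cells by a split of the mice described below. For these lists differences between the mice were not told apart from genotype.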

How the results depend on the processing

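The edgeR fit without robust dispersion estimates was chosen after seeing the data; the other alternatives were planned. The genotype counts of 16 genes in FO and 14 in MZ B cells kept their size with limma-voom (18 and 13), RLE factors (16 and 14), immunoglobulin genes left out of the scaling (16 and 14), the animal number series as a covariate (21 and 14) and all 12 libraries in the fit (18 and 16). With that covariate and all 12 libraries together they were 23 and 21. DESeq2 gave 42 and 35, with all 16 and 14 genes among them, and no low-count filter gave 140 and 95; the cause was not tested. The filter at 5 CPM, which tests fewer genes, gave 13 and 6, and glmTreat, which asks for more than a fold of 1.5, gave 7 and 4. The fit without robust dispersion estimates gave 14 and 7. With the replicate block the counts were 25 in FO and 57 in MZ B cells, where the numbers do not pair the libraries (correlations -0.0654, 0.362 and 0.365 once group means were removed; replicate 1 did not correlate best with its own number), and the reported ZBTB24 targets in MZ no longer passed with an estimated correlation (adjusted p = 0.135).

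Leaving out 1 library gave 11 to 31 genes in FO B cells (31 without FO CKO replicate 3) and 5 to 34 in MZ B cells (7, 5 and 9 without MZ Control replicates 1, 2 and 3, and 34 without MZ CKO replicate 3). For MZ against FO the counts were 1025 in control and 664 in CKO mice with glmTreat, and 7805 and 6333 with the mouse as a block. Leaving out 1 library gave 3585 to 5012 genes in control and 1898 to 2884 in CKO mice (1898 without FO CKO replicate 1). Fewer libraries lower the power of a test; why some counts were higher was not tested. The test of differing genotype effects gave 4 genes with the mouse as a block and 0 under each other alternative run for it, each library left out included. Those other alternatives did not take the mouse into account. The animal number series was a covariate only in the genotype comparisons. The overlap of FO and MZ was 24 genes with DESeq2, against 12, and 13 at an adjusted p under 0.1 or with all 12 libraries.

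Of the 30 lists, 7, 10, 6, 9 and 5 passed camera (FO, MZ, control, CKO and the difference of effects), 1, 1, 1, 2 and 0 passed with an estimated correlation, and 2, 1, 12, 6 and 0 passed fry, which tests another question. No named gene changed direction past the threshold under any alternative. Over named genes and alternatives, calls were lost in 29 cases in FO, 44 in MZ, 100 in control and 105 in CKO mice, and gained in 22, 16, 3 and 23. Taf6 in FO B cells passed under all 18 alternatives (highest adjusted p = 0.02248). Depth limits the genes with few counts, where folds rest on as few as 0 to 8 control counts.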

Other observations

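The tests in this part other than the counts over splits were chosen after the results were seen, and so were the genes named in it. Some neighbours of called genes had values that differed in the same direction. Mcoln2, which lies beside Mcoln3 on chromosome 3 and also encodes an endolysosomal channel, was at 39.6 ± 6.68 CPM in FO control and 64.0 ± 6.74 CPM in FO CKO libraries (log2 0.70, adjusted p = 0.475 in edgeR and 2.677e-05 in DESeq2). In MZ B cells Mcoln2 was at 70.4 ± 6.58 CPM in control and 97.8 ± 7.52 CPM in CKO libraries (log2 0.47, adjusted p = 0.1993 in edgeR and 0.003647 in DESeq2). St6galnac2, a sialyltransferase gene near St6galnac1 on chromosome 11, was at 25.1 ± 3.30 CPM in FO control and 41.7 ± 5.90 CPM in FO CKO libraries (log2 0.73, adjusted p = 0.2145 in edgeR, 0.00734 with the replicate block and 2.134e-05 in DESeq2).

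Granule genes of neutrophil precursors peaked in the same animal numbers in both cell types. Ngp was highest in replicate 2 of each group, at 29.8 CPM in FO control, 73.2 CPM in FO CKO, 22.3 CPM in MZ control and 53.1 CPM in MZ CKO libraries, against 4.12 to 15.9 CPM in the other 8 libraries. Ltf in replicate 2 was at 43.0, 118, 30.5 and 73.4 CPM in the same order. Xist was at 106 to 452 CPM in the 12 libraries, and the Y-linked genes Ddx3y and Eif2s3y had 0 counts in each, while the Y-linked Kdm5d had 74 to 180 counts per library.

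Of 18 genes called by genotype in FO or MZ B cells, 6 lay on chromosome 10, all within 25 Mb of Zbtb24, and with called genes within 1 Mb of each other counted once these were 3 of 14 loci. A tract of another strain carried along with the targeted allele may account for these 6, and cannot be told apart from loss of ZBTB24 for them, as tract and allele would go together in every CKO mouse. Variants acting within such a tract leave out the other 12, which lie on 7 other chromosomes and include Axin2 and Taf6; effects of the tract on genes elsewhere were not tested. Reads of Hmgb1 counted at a fixed share on Hmgb1-ps8 are argued against, as the lowest CKO library had 59.1 Hmgb1-ps8 counts per 1000 Hmgb1 counts and the highest control library 0.852. Loss of ZBTB24 itself stays open for all 18 genes.

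A split of the mice other than by genotype called more genes than genotype did, in both cell types. It parts mice 1505, 2003 (control) and 2002 (CKO) from 1507 (control), 1512 and 1514 (CKO), and it called 31 genes in FO and 73 in MZ B cells, 23 of them in both, including 17 heavy-chain V genes such as Ighv1-14 (0.198, 12.7 and 0.22 CPM in FO control and 10.1, 7.30 and 0.183 CPM in FO CKO libraries). Of the 9 FO genes other than immunoglobulin genes 6 lay on chromosome 12 (5 of 8 loci; one-sided Fisher's exact test, p = 1.52e-06), and of 48 in MZ 11 did (6 of 41 loci, p = 0.0017), so a candidate explanation for the heavy-chain genes is 1 or more strain tracts on chromosome 12 carried by some of the mice; a tract around the heavy-chain locus alone would not hold 3110053B16Rik and Gm10478, at 20.9 Mb, or Rnf144a, at 26.3 Mb, and the 37 other MZ genes, such as Vim and Cxcr4, stay unexplained. Expanded B cell clones stay open for the V genes. The split also called 4 light-chain V genes in MZ B cells (Igkv4-86, Igkv8-21, Igkv8-19 and Iglv1), which lie on other chromosomes. Clones also stay open for the 4 genes other than immunoglobulin genes on chromosome 12 called in both cell types. These are Tmem121, 3110053B16Rik with the overlapping Gm10478, and Rapgef5. They make up 3 loci, the fewest taken to argue against clones, and that limit was set after the result was seen. Tmem121 also lies near the heavy-chain V genes. No other biological explanation was tested, since the labels give no trait that parts the mice in this way. Some of the 37 genes shifted toward FO levels in MZ libraries of mice 1507, 1512 and 1514. Vim was at 148, 151 and 164 CPM there, against 81.9 to 98.3 CPM in other MZ and 352 to 448 CPM in FO libraries. Others, such as Antxr2, shifted away (34.1, 29.1 and 25 against 44.3 to 47.7 CPM, with 47.2 to 64.4 CPM in FO). Fcer2a was at 69.6 ± 4.29 CPM in MZ control and 558 ± 33.5 CPM in FO control libraries. Carry-over of FO B or T cells into MZ libraries was not tested.

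For every count, 10 splits of the libraries are too few for a share under 0.05. By genotype, the real split gave 16 genes in FO and 14 in MZ B cells, and the highest other gave 31 and 73, so 2 of the 10 splits gave as many in each; the highest MZ count, several times the real one, points to a structure of the samples, which genes on chromosome 12 cover in 28 of the 31 FO calls and 32 of the 73 MZ calls. In FO B cells the replicate numbers were treated as pairs from their correlations alone, though the paired control and CKO libraries come from different animals. There the other splits that part all 3 pairs gave 0, 1 and 0 genes. For genes called in both cell types the real split gave 12, the highest other 23, and 2 of the 10 gave as many. Between MZ and FO B cells the real splits gave 4977 genes in control and 3243 in CKO mice, the highest other 0 in each, and 1 of the 10, the real one, gave as many. For differing genotype effects without the block the real and the highest other value were 0, so all 10 splits gave as many. For lists past camera the real splits gave 7 in FO, 10 in MZ, 6 in control, 9 in CKO mice and 5 for the difference of effects, the highest others 12, 15, 12, 14 and 7, and 8, 5, 8, 5 and 2 of the 10 gave as many.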
